A study of Mus musculus with 8 samples.

How the data were processed

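The samples are CD4+ T cells of mouse spleen; per the labels, total RNA was extracted with Trizol and made into Illumina libraries, with no statement on how messenger RNA was selected. The deposited table gives whole-number read counts per gene for the 8 libraries, which the authors left unnormalised. The submitters' processing notes name HISAT2 2.0.5, DESeq and the human builds hg38 and GRCh38. The gene identifiers are mouse, and 53585 of the 54495 rows found in GENCODE M21 (98.3%) have start and end positions identical to that annotation of GRCm38, so GRCm38 is used for positions here. The table holds 54532 gene rows, and 0 rows name no gene. The counting program, its strand setting and the annotation release are not given in the sources used here. A treatment note in the labels mentions human donors, although organism and genotype are those of mice, and it was not used. Because the strand setting is unknown, genes that overlap another gene, or have close paralogs, are uncertain where named so.

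Libraries were grouped by the genotype in their labels, 4 Ddx58 KO and 4 WT. Total counts per library were 15938083 to 17961485. Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr with a minimum count of 10, robust quasi-likelihood fit, quasi-likelihood F test) and Benjamini-Hochberg adjustment over 13457 genes, with 0.05 as the threshold. Log2 fold changes are KO minus WT. Standard errors were computed as the absolute log2 fold change divided by the square root of the F statistic, and are approximate. CPM values use TMM-scaled library sizes, and errors are SD over 4 libraries. The biological coefficient of variation was 16.1%.

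Gene lists (29) and cell type marker lists (14) were written before the data were examined and tested with camera in limma 3.58.1 (preset correlation 0.01), with an estimated correlation and fry beside it. Fry asks whether the members of a list move one way on balance and does not compare the list with other genes. A mixed form of fry asks for change in either direction. Glycolysis has more tested members than symbols because 1 symbol has more than 1 identifier. Library shares, the summed CPM of each marker list and Ddx58 were tested by exact two-sided permutation; the test of the sums was added after seeing the data. The 4 against 4 design gives a smallest p of 0.0286.

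Genes were named by a rule written before the data were examined. It took Ddx58, the 12 largest increases and 12 largest decreases among called genes with a mean of at least 1 CPM, no overlap between the groups and an established symbol, a fixed panel of 18 genes (some of them not reported here), and up to 4 members with the smallest p of each list that passed and of the interferon, Th1, Th17, Treg and Tfh lists. Other called members of lists, Ctla4, Cd8a and genes of the closing observations were named after their values were seen.

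The pipeline was tested on simulated counts for the 13457 genes with 4 libraries per group, 50 genes at each size of change. It recovered 36%, 70%, 82% and 88% of genes changed by 0.5, 1, 1.5 and 2 on the log2 scale, and 6.94% of its calls were genes left unchanged. Camera called 2 of 2 shifted simulated lists and 0 of 18 unchanged ones. The simulated genes varied independently, so this does not test camera on lists whose members vary together. The correlation estimated in the data was 0.196 for the Th2 list, 0.44 for Treg and 0.549 for type I interferon-stimulated genes. Alternatives were other size factors, DESeq2 1.42.0, limma-voom, other filters, protein-coding genes alone, the replicate number as a block, a surrogate variable (sva 3.50.0), other thresholds and each library left out. Removal of each library's trend with GC content and gene length was added after seeing the data.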

Results

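RNA sequencing measured gene expression in CD4+ T cells, the helper T-cell lineage, from mouse spleen. The series holds 4 libraries from mice lacking Ddx58 (Ddx58 KO) and 4 from wild-type (WT) mice, numbered 2 to 5 in each group. Ddx58 encodes RIG-I, a cytosolic sensor of viral RNA that signals through the adaptor MAVS to type I interferon genes. The total count per library ranged from 15938083 to 17961485, and 13457 genes passed the filter on low counts. The sample titles carry a prefix that the labels do not expand, so the activation state of the cells is left unstated. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Replicates of a group differed well beyond counting noise, with a chi-square per gene of 7.95 to 39.5 for the pairs within a group.

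The comparison of the genotypes addresses how loss of RIG-I changes gene expression in CD4+ T cells, within a study of endogenous retroviruses, T-cell differentiation and lupus. The targeted gene was examined in every library first. Ddx58 (ENSMUSG00000040296) lies on the minus strand of chromosome 4 from 40203773 to 40239828 in GRCm38. Its counts in the WT libraries 2 to 5 were 660, 1000, 715 and 1153, and in the KO libraries 159, 170, 204 and 113. The mean normalised level was 51.7 ± 11.2 CPM in WT and 9.53 ± 2.26 CPM in KO (SD, n = 4 each), so that KO libraries held 18.4% of the WT level. The log2 fold change was −2.44 (SE 0.20; edgeR quasi-likelihood test, adjusted p = 0.00244), and the exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 allows. Counts over the whole gene cannot tell residual transcript without the deleted part from intact transcript, and the deleted part is not given in the sources used here.

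Loss of Ddx58 went with changed expression of 394 genes, of which 164 were higher and 230 lower in KO. Among the genes that rose, Eomes, a T-box transcription factor best known from cytotoxic lymphocytes, went from 2.86 ± 0.79 to 21.01 ± 13.20 CPM (7.34-fold, log2 2.88, SE 0.46, adjusted p = 0.0190). Myb, a transcription factor of blood progenitors and lymphocytes, went from 33.6 ± 8.6 to 160.5 ± 68.0 CPM (4.77-fold, log2 2.25, SE 0.34, adjusted p = 0.0168). Id3, an inhibitor of E-protein transcription factors, rose 4.13-fold, and Tnfsf11, which encodes the cytokine RANKL, rose 3.92-fold. The other genes named for large increases were Cyr61 (log2 3.55), Nebl (3.10), Pla2g4f (2.74), Dclk1 (2.44), Dhrs9 (2.17), Ms4a4b (2.09), Ms4a4c (2.05) and Nrn1 (1.93). Cyr61 was scarce, at 2.47 CPM in KO and 0.198 CPM in WT, and its log2 fold change was 4.82 without WT 5. Ms4a4b and Ms4a4c belong to a family of similar genes, and Nrn1 overlaps Fars2, so their reads may be partly shared.

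Among the genes that fell, Il10, an anti-inflammatory cytokine, went from 13.0 ± 3.7 CPM in WT to 1.61 ± 1.12 CPM in KO (8.05-fold lower, log2 −3.01, SE 0.43, adjusted p = 0.0132). Il4, the cytokine that defines Th2 cells, went from 15.2 ± 6.3 to 1.81 ± 1.68 CPM (8.31-fold lower, log2 −3.05, SE 0.58, adjusted p = 0.0315). Tnfrsf8, which encodes CD30, went from 98.9 ± 26.8 to 14.8 ± 15.2 CPM (log2 −2.74, SE 0.55, adjusted p = 0.0356). Myo6, an unconventional myosin, went from 30.3 ± 13.2 to 2.65 ± 1.06 CPM (log2 −3.51, SE 0.36, adjusted p = 0.00702), and Plcd1, a phospholipase C, from 5.57 ± 0.72 to 0.396 ± 0.254 CPM (log2 −3.79, SE 0.37, adjusted p = 0.00272). Cyp11a1, the enzyme that starts steroid synthesis from cholesterol, had a log2 fold change of −3.33, and Akr1c18, a hydroxysteroid dehydrogenase with close paralogs, one of −3.61. The remaining genes named for large decreases were Efna5 (−3.65), Cacna1c (−3.51), Timd2 (−3.27), Cxcl3 (−3.11) and the endothelin gene Edn1 (−3.02). Cacna1c overlaps Dcp1b, which had 5.14 times its counts, so its value is uncertain. Without KO 4 the log2 fold changes were −4.79 for Cxcl3, −4.70 for Cacna1c, −4.55 for Cyp11a1, −4.46 for Timd2, −3.87 for Il4 and −3.78 for Tnfrsf8, and Cacna1c had −2.89 without WT 2 and did not pass (adjusted p = 0.103).

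Of the 394 called genes, 195 changed by at least 1 on the log2 scale (66 higher, 129 lower), and in 389 the KO and WT libraries did not overlap. Over all tested genes 10.2% showed no overlap, against 2.86% by chance. The count depended on single libraries. It was 9 without KO 2, 30 without WT 3, 64 without WT 4, 76 without WT 2, 114 without KO 3, 145 without KO 5, 247 without WT 5 and 897 without KO 4. DESeq2 called 953 genes, and all 394 were among them. Of the 45 named genes past the threshold, 45 kept their direction in every refit and 4 (Ddx58, Plcd1, Myo6 and Nrn1) stayed past it whichever library was left out. Kept direction is weak evidence, since leaving out 1 library can hardly reverse a gene whose groups do not overlap.

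**Figure D1:**
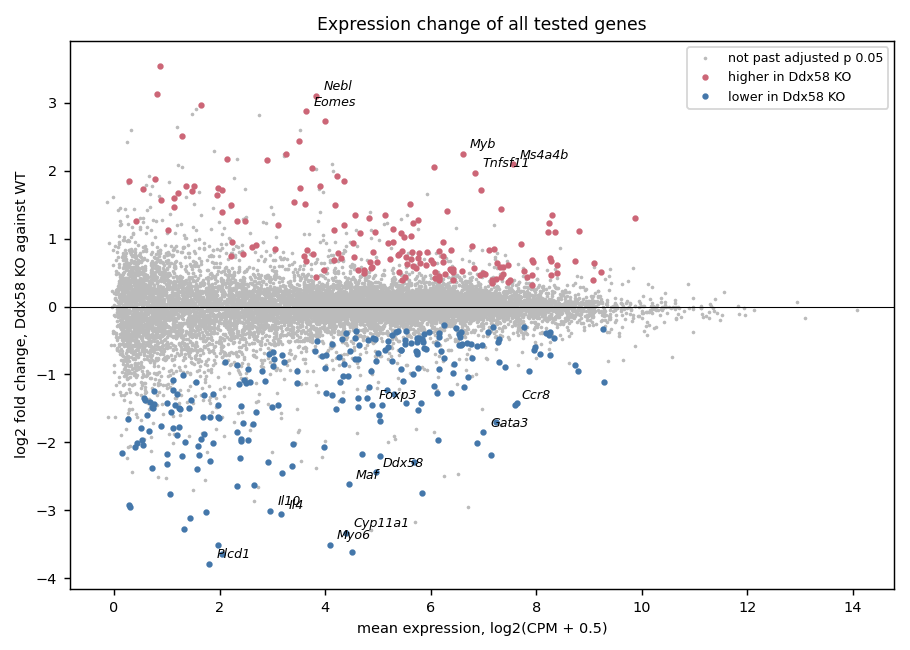
Log2 fold change of Ddx58 KO against WT (vertical axis) against mean expression, as log2 of CPM plus a pseudocount of 0.5 (horizontal axis), for all 13457 tested genes. Red points are the 164 genes higher and blue points the 230 genes lower in KO at an adjusted p under 0.05, and grey points are the rest.

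Genes of the Th2 programme, which serves defence against helminths and drives allergic responses, were lower in KO. Of 23 tested members, 9 fell, 0 rose and 14 did not pass over all genes, while 17 were lower when adjusted over the list alone. Gata3, the transcription factor that directs Th2 development, went from 198.6 ± 23.5 to 54.9 ± 32.8 CPM (3.61-fold lower, log2 −1.85, SE 0.35, adjusted p = 0.0326). Maf, which drives Il4 transcription, fell 6.12-fold (log2 −2.61, adjusted p = 0.0175), and the chemokine receptor genes Ccr4 (log2 −1.70) and Ccr8 (−1.45) fell too. The other members that fell, beyond Il4 and Il10, were Il4ra, Il17rb and Il1rl1. The median log2 fold change of the list was −1.84 (limma camera with a preset correlation of 0.01, adjusted p = 2.99e-18; adjusted p = 0.143 with an estimated correlation; fry, adjusted p = 0.0158). Gata3 passed the threshold in 1 of the 8 fits that left out a library, and Il4 in 2, with log2 fold changes from −2.31 to −1.64 and from −3.87 to −2.74.

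Genes of regulatory T cells (Treg), the lineage that restrains immune responses, were lower as well. Of 29 tested members, 11 fell, 0 rose and 18 did not pass, and 24 were lower when adjusted over the list alone. Foxp3, the defining transcription factor of the lineage, went from 42.5 ± 15.0 to 15.6 ± 3.0 CPM (2.72-fold lower, log2 −1.45, SE 0.25, adjusted p = 0.0257). Ecm1 fell 4.54-fold (log2 −2.18), Lrrc32, which encodes the TGF-beta-docking protein GARP, 2.78-fold (log2 −1.47) and Socs2, a feedback inhibitor of cytokine signalling, 1.86-fold (log2 −0.90). The other members that fell were Il10, Gpr83, Ccr8, Itgae, Tigit, Penk and Fgl2. Ctla4, also on the list, had a log2 fold change of 0.06 (adjusted p = 0.841). The list's median log2 fold change was −0.79 (camera, adjusted p = 4.74e-26; adjusted p = 0.215 with an estimated correlation; fry, adjusted p = 0.0359). Il10 and Ccr8 are on both the Th2 and the Treg list.

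The list of IL-2 and STAT5 response genes moved the same way by camera (median −0.29, adjusted p = 1.84e-09; adjusted p = 0.382 with an estimated correlation), with a median of −0.451 without KO 4, −0.2 without KO 5 and −0.19 with 1 surrogate variable. Of its 32 members, 6 fell and 0 rose, and 13 were lower when adjusted over the list alone. These were Socs2, Gpr83, Il4ra, Tnfrsf8, Ahr and Cish over all genes. Socs2 and Gpr83 are also on the Treg list, Il4ra on the Th2 list and Ahr on the Th17 list, so the lists are not independent. Il2ra, which encodes the IL-2 receptor alpha chain, stood at 1139 ± 354 CPM in KO and 1899 ± 267 CPM in WT, a difference that did not pass (log2 −0.74, adjusted p = 0.0847).

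Type I interferon-stimulated genes stood higher in KO as a group, while few passed singly. Of 54 tested members, 48 had a positive log2 fold change, 1 (Ms4a4b) rose and 53 did not pass over all genes, and 25 were higher when adjusted over the list alone. The median log2 fold change was 0.47 (camera, adjusted p = 4.11e-16; adjusted p = 0.385 with an estimated correlation; fry, adjusted p = 0.145). Ms4a4b encodes a membrane protein of T cells and went from 71.1 ± 34.9 to 303.8 ± 66.7 CPM (log2 2.09, adjusted p = 0.0212). Members that did not pass were Mx2 (log2 1.84, adjusted p = 0.0553), Ifi203 (2.001, adjusted p = 0.0556, with reads possibly shared with Mndal) and Ifi209 (1.39, adjusted p = 0.0604). The RNA sensor gene Ifih1 had log2 0.86 (adjusted p = 0.0943), Ifit1 1.24 (adjusted p = 0.164) and Isg15 0.75 (adjusted p = 0.202). The interferon-gamma response list had a median of 0.26 over 41 members (camera, adjusted p = 0.00171; adjusted p = 0.542 with an estimated correlation), and of 0.125 without KO 5 or 0.173 without WT 2. Gbp5, a guanylate-binding protein, was the member of that list that rose (log2 1.22, adjusted p = 0.0397), and the other 40 did not pass, among them Igtp (0.44), Irgm2 (0.57) and Socs1 (−0.73). Igtp and Irgm2 overlap each other. The summed levels of macrophage and monocyte markers (138.4 ± 19.0 CPM in KO, 91.1 ± 15.0 CPM in WT), CD8 T-cell markers (64.7 ± 14.5 and 33.8 ± 7.0 CPM) and NK-cell markers (46.2 ± 14.6 and 18.9 ± 5.4 CPM) stood higher beside these lists, with no overlap of the groups. Each had an exact permutation p of 0.0286 and an adjusted p of 0.08 over 14 sums. Eomes, at 21.01 CPM in KO and 2.86 CPM in WT, is counted in both the CD8 and the NK sum, so these are not independent. Without Eomes the groups overlap in both sums. In KO 3, Eomes made up 13.61 CPM of a CD8 sum of 49.53 CPM and of an NK sum of 34.2 CPM. In WT 3 it made up 2.092 CPM of sums of 42.54 and 23.65 CPM. Most of the NK sum was Eomes and Txk, the latter at 21.27 CPM in KO and 12.48 CPM in WT.

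**Figure D2:**
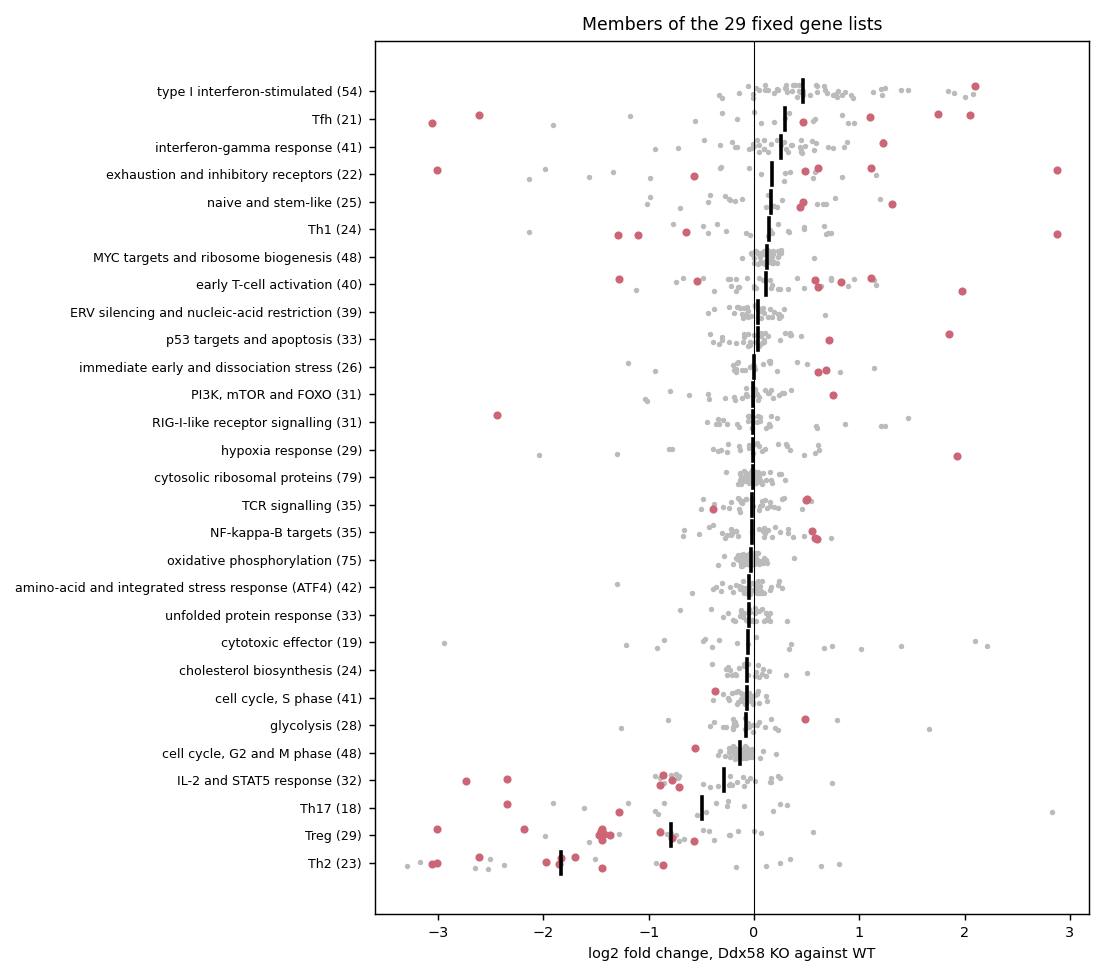
Log2 fold change of Ddx58 KO against WT (horizontal axis) for the tested members of the 29 fixed gene lists, with the number of members in brackets. Red points are members with an adjusted p under 0.05 over all genes, grey points are the rest and black bars are list medians, from −1.84 for Th2 to 0.47 for type I interferon-stimulated genes.

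The Th1 list did not pass (median 0.14 over 24 members, camera, adjusted p = 0.934), and its median ran from −0.00664 (without KO 5) to 0.258 (without WT 5) with 1 library left out. Its regulator Tbx21 stood at 99.9 ± 6.6 CPM in KO and 102.7 ± 13.0 in WT (log2 −0.04, adjusted p = 0.893), and the cytokine gene Ifng at 22.0 ± 10.2 and 23.2 ± 15.5 CPM (log2 −0.08, adjusted p = 0.967). Within the list Eomes rose, and Cxcr3 (log2 −1.10), Il12rb1 (−0.65) and Hlx (−1.29) fell. The Th17 list was lower by camera (median −0.50 over 18 members, adjusted p = 0.000387; adjusted p = 0.353 with an estimated correlation), with 2 members that fell. These were Batf (log2 −1.28, adjusted p = 0.0171), a transcription factor also used by other helper lineages, and the aryl hydrocarbon receptor gene Ahr (−2.35, adjusted p = 0.0377; −2.94 without KO 4). Ccr6 had log2 2.83 (adjusted p = 0.107; 4.66 and adjusted p = 0.0207 without WT 5) and Tmem176a −0.92 (adjusted p = 0.122, with reads possibly shared with Tmem176b). Il17a was too scarce to test, with counts of 0, 13, 2 and 2 in WT and 0, 0, 1 and 0 in KO.

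Members of the follicular helper (Tfh) list, whose cells help B cells, went both ways. Id3, Pou2af1 (log2 1.75), Tcf7 (0.46) and Sh2d1a rose, Maf and Il4 fell, and 15 of 21 did not pass. The list's median was 0.29 and its mean 0.01 (camera, upward, adjusted p = 0.0306; adjusted p = 0.353 with an estimated correlation). The call was lost without WT 2 (adjusted p = 0.0784), KO 4 (0.0617) or KO 5 (0.0837), and with voom (0.114), 1 surrogate variable (0.0618) or GC and length trends removed (0.103). Bcl6, the Tfh regulator, had log2 0.95 (adjusted p = 0.252), Cxcr5 0.19 (adjusted p = 0.838, with reads possibly shared with Bcl9l) and Il21 −1.91 (adjusted p = 0.214; −3.29 and adjusted p = 0.00866 without KO 4). Il21 stood at 46.75 CPM in KO 4 and at 3.23 to 9.21 CPM in the other KO libraries.

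The naive and stem-like list did not pass (adjusted p = 0.156), but Ccr7, the receptor that guides T cells to lymph nodes, rose from 538 ± 183 to 1334 ± 253 CPM (log2 1.31, adjusted p = 0.0271), with Tcf7 and Bach2 (log2 0.44). In the early activation list (adjusted p = 0.204; 0.0339 without WT 5), Tnfsf11, Nr4a3, Cd69, Nr4a1 and Rel rose, and Batf and Egr2 fell. Cd44 had log2 0.73 (adjusted p = 0.0809) and Il2 0.95 (adjusted p = 0.481; 0.27 without KO 5). In the exhaustion list (adjusted p = 0.441), Eomes, Nr4a3, Nr4a1 and Vsir rose, and Il10 and Tigit fell.

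Growth-related lists moved little. The G2 and M phase list had a median of −0.13 over 48 members (camera, adjusted p = 0.000317; adjusted p = 0.996 with an estimated correlation), with Cdc25b (log2 −0.56) the member that fell; without KO 4 the call was lost (adjusted p = 0.119), and without WT 4 the median was −0.0857. Its other named members, which did not pass, were Ccnb2 (−0.32), Cdca3 (−0.24) and Ttk (−0.34). The S phase list had a median of −0.07 (adjusted p = 0.0260; adjusted p = 0.996 with an estimated correlation), with Tk1 (log2 −0.37) the member that fell, and Cdt1 (−0.39), Mcm5 (−0.30) and Mcm2 (−0.25) not passing. Its call was lost without WT 2 (adjusted p = 0.253), WT 4 (0.297) or KO 4 (0.559), and its median ran from −0.135 (without WT 3) to −0.0243 (without KO 4). The list of MYC targets and ribosome biogenesis had a median of 0.12 (adjusted p = 0.00176; adjusted p = 0.996 with an estimated correlation), and 0 of 48 members passed, Odc1 (0.57), Hspd1 (0.24), Gnl3 (0.26) and Wdr43 (0.19) included. Its call was lost without KO 5 (median 0.0488, adjusted p = 0.297) or WT 3 (median 0.0659, adjusted p = 0.0777), and with 1 surrogate variable (adjusted p = 0.0837).

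RIG-I-like receptor signalling did not pass (median −0.01 over 31 members, adjusted p = 0.811), and Ddx58 was the member that fell. Mavs stood at 31.3 ± 2.4 CPM in KO and 32.5 ± 3.6 in WT (log2 −0.05, adjusted p = 0.861). The list of genes for silencing of endogenous retroviruses and restriction of nucleic acids had 0 of 39 members past the threshold (adjusted p = 0.811). Expression of endogenous retroviruses was not analysed here, since the table holds annotated genes. Camera also gave no call for cytotoxic effector genes (adjusted p = 0.851), glycolysis (0.292), hypoxia (0.934), oxidative phosphorylation (0.286), cytosolic ribosomal proteins (0.744), the ATF4 stress response (0.498), the unfolded protein response (0.498), cholesterol synthesis (0.498), NF-kappa-B targets (0.995), p53 targets (0.441), PI3K, mTOR and FOXO genes (0.498), TCR signalling (0.851) or immediate early genes (0.496). Without KO 5, lower calls appeared for glycolysis (adjusted p = 0.000202), oxidative phosphorylation (0.0141) and cholesterol synthesis (0.0245). Oxidative phosphorylation was also called lower without WT 2 (0.0470) and with 1 surrogate variable (0.00689), and cytotoxic effector genes were called lower without KO 4 (0.00964). Among lists without a camera call, NF-kappa-B targets had 3 called members, all higher, and TCR signalling 2 higher and 1 lower. In p53 targets and immediate early genes 2 each were higher, and in hypoxia, glycolysis and PI3K, mTOR and FOXO genes 1 each. With an estimated correlation 0 of the 29 lists passed, and by fry 2 did, Th2 and Treg. The mixed form of fry passed for hypoxia (adjusted p = 0.000501), NF-kappa-B targets (0.00208) and TCR signalling (0.00413), among others, but not for oxidative phosphorylation (0.509).

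**Figure D3:**
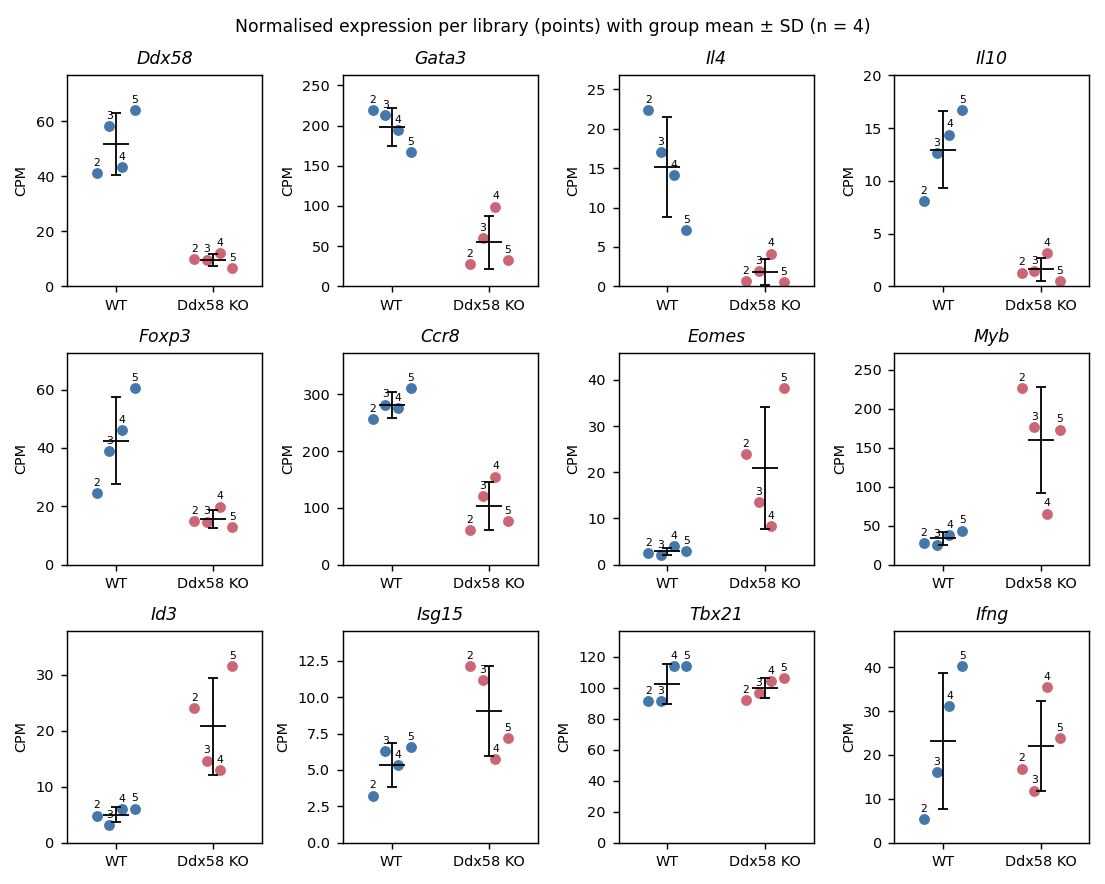
Normalised level in CPM (vertical axis) of 12 genes in each of the 4 WT (blue) and 4 Ddx58 KO (red) libraries, with the replicate number above each point. Black bars show the group mean ± SD; Ddx58 was 51.7 ± 11.2 CPM in WT and 9.53 ± 2.26 CPM in KO, while Tbx21 and Ifng overlapped between the groups.

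Markers of other cell types were tested beside these groups. The T-cell identity list had a median log2 fold change of −0.01 over 12 members (camera, adjusted p = 0.846), and Cd5 was the member that rose. The CD8 T-cell list was higher in KO (adjusted p = 0.00487; adjusted p = 0.216 with an estimated correlation), with Eomes and Ly6c2 past the threshold, while Cd8a was 11.79 CPM in KO 4 and at most 3.78 CPM in the other libraries. The NK-cell list was higher (adjusted p = 0.0234; adjusted p = 0.339 with an estimated correlation), with Eomes past the threshold. The plasma-cell list was lower (adjusted p = 0.00487; adjusted p = 0.216 with an estimated correlation), though none of its 5 members passed and activated T cells also express its members Prdm1 and Xbp1. The macrophage and monocyte list did not pass (median 0.35, 9 of 11 members positive, adjusted p = 0.0625), and Ly6c2 was the member that rose. Its gene Ctss made up most of the sum, at 89.9 CPM in KO and 53.5 CPM in WT, while Lyz2 was 5.93 CPM in KO 5 and at most 0.998 CPM in the other libraries. No call was made for dendritic cells (0.553), neutrophils (0.771), B cells (0.625), gamma-delta T cells (0.578), mast cells and basophils (0.970), erythroid cells (0.970), platelets (0.531), stromal cells (0.531) or sex-linked genes (0.801). Summed levels did not overlap for platelet markers, at 77.9 ± 34.5 CPM in KO and 153.3 ± 19.3 CPM in WT, or for gamma-delta T-cell markers, at 1.18 ± 0.36 and 2.16 ± 0.46 CPM (exact permutation p = 0.0286, adjusted p = 0.08 each). Most of the platelet sum was Itgb3, an integrin gene, at 71.8 and 146.2 CPM, with KO 4 at 122.1 CPM, while Pf4 and Ppbp were at or near 0; the sum stood lower beside the Th2 and Treg lists. Mitochondrial genes took 1.97 ± 0.05% of counts in KO and 1.75 ± 0.16% in WT, and the top 50 genes 13.65 ± 0.22% and 14.03 ± 0.20% (exact permutation tests, p = 0.0571 and 0.0286, both 0.2 when adjusted over 7 quantities).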

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

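The tests of fewer Foxp3-expressing cells, of RNA from myeloid or dendritic cells and of 1 library setting the interferon difference were chosen after the results were seen, as was the GC and length correction; the others were planned before the data were examined. In 168 sets of 4 libraries, 14 had a library far from the other 3, where chance gives about 1 in 20.

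KO 4 accounted for 7 of these. Its Tnfrsf8 level was 37.66 CPM (others 6.57 to 7.55), Il21 46.75 CPM (3.23 to 9.21), Batf 60.59 CPM (30.17 to 35.23), Socs2 47.28 CPM (33.80 to 34.79), Cxcr3 7.097 CPM (3.089 to 3.561) and Cxcl3 1.408 CPM (0.0576 to 0.229), and it had a count for 22826 genes (21892 to 21957). Over 393 called genes, Ddx58 left out, each KO library was placed on the way from the mean of the other KO libraries (0%) to the WT mean. The median position was 39.9% for KO 4, 0.499% for KO 3, −15.2% for KO 5 and −33.3% for KO 2. The same position for the Ddx58 level was 18.7%, 3.32%, −30% and 4.95%.

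WT 2 stood apart for Myo6 at 49.82 CPM (others 20.69 to 25.63) and Lrrc32 at 26.44 CPM (37.31 to 38.82). WT 3 stood apart for Tnfrsf8 at 138.8 CPM (80.65 to 89.79). WT 5 stood apart for Ccr6 at 4.728 CPM (0.312 to 0.608). WT 4 had a count for 23156 genes (21241 to 21382) and 14.32% of its counts in the top 50 genes (13.91 to 13.96). KO 2 stood apart for Gpr83 at 14.31 CPM (17.71 to 18.19).

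The number of changed genes was weighed against 3 technical explanations. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave at least 394 calls, the genotype split itself, and the highest of the others gave 0. That is the smallest share that 35 splits allow. The other splits mix the genotypes within each group, which widens their spread, so their lack of calls does not exclude chance. Called genes showed no clear concentration near the targeted locus, with 1.02% of them within 10 Mb of Ddx58. There 4 of 118 tested genes were called, namely Bach2, Nr4a3, Rragd and Tbc1d2, and elsewhere 389 of 13338. Fisher's exact test gave an odds ratio of 1.17 (confidence interval 0.311 to 3.1, p = 0.779). An interval this wide does not exclude some clustering. With each library's GC and length trends removed, 90.1% of the calls remained in the same direction. Loss of Ddx58 is a candidate explanation as a hypothesis, but differences of background, litter or preparation day between the genotypes are not in the labels and stay open, untested.

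Treg and Th2 genes were lower in KO. Dilution of T cells by other cells would lower T-cell identity genes too, and their median log2 fold change was −0.00932 (interval over resampled genes −0.136 to 0.128). Fewer Foxp3-expressing cells alone would lower Treg genes at least as much as Th2 genes. The 21 tested Th2 members outside the Treg list had a median of −1.84, and the 27 Treg members outside the Th2 list −0.775. The difference was −1.06, with an interval over resampled genes of −1.79 to 0.0266, which reaches 0. Such intervals take genes as independent and leave out the spread between libraries. Fewer Foxp3-expressing cells alone stays open as an explanation. A lower share of Th2-like cells, of Treg cells or of both, or lower transcription per cell, may each underlie the pattern and were not separated. Both list calls end when the correlation between genes is estimated, so the group-level evidence rests on the preset correlation and on fry.

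Type I interferon-stimulated genes stood higher in KO. No 1 library set the difference, since the lowest list median over the 8 fits without a library was 0.347 (highest 0.585). Against RNA from myeloid or dendritic cells, 12 of their transcripts summed to 32.0 ± 10.5 CPM in KO and 36.7 ± 8.7 CPM in WT beside 2937 ± 467 and 2207 ± 333 CPM for the interferon list without Ms4a4b, where KO 4 (2349 CPM) lay below WT 5 (2673 CPM), and Csf1r, C1qa, C1qb, C1qc, Cd14, Adgre1, S100a8, S100a9 and Siglech reached at most 0.9115 CPM in any library; both sets were chosen with levels already seen. Most of the 12-transcript sum was Flt3 (16.54 CPM in KO, 23.89 CPM in WT) and Zbtb46 (11.98 and 10.45 CPM). Its lower level in KO rests mainly on Flt3. RNA from myeloid or dendritic cells still cannot be told apart from a change within T cells for part of the rise. The 24 pooled markers were the fixed lists without members of the type I list. Their median was 0.268, above 0 and below the list's 0.47 (0.0984 to 0.394 over resampled genes, which leaves out the spread between libraries). These markers still hold Cd74, H2-Aa, H2-Ab1, H2-Eb1 and Ciita of the interferon-gamma response list. Genes near the floor set no bound on the share. The call of the type I list is also lost with an estimated correlation (adjusted p = 0.385).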

How the results depend on the processing

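The GC and length correction was chosen after seeing the data; the other alternatives were planned. Other size factors, voom, the CPM filter, protein-coding genes alone and the GC and length correction gave 385 to 444 calls. DESeq2 gave 953 calls (418 higher, 535 lower), no low-count filter 621 (271, 350) and 1 surrogate variable 733 (370, 363). An adjusted p under 0.01 left 11 (3, 8) and a log2 change of at least 1 left 195 (66, 129), as stricter thresholds must. Without 1 library the count ran from 9 (without KO 2) to 897 (without KO 4), with 3 to 364 higher and 6 to 533 lower. In each of these fits 394 of 394 called genes kept their direction. That was largely fixed in advance, since 389 of the called genes had no overlap of the groups. Apart from the thresholds, the cause of the differing counts was not tested. Same-numbered libraries correlated by 0.0525, 0.104, −0.125 and 0.292 and 0 of 4 KO libraries matched their own number best. That gives no sign that the numbers pair the samples, but 4 libraries per group are too few to exclude it. With the replicate block the count was 245 (105, 140).

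With an estimated correlation 0 gene lists and 0 marker lists passed, and fry left 2 gene lists and 2 marker lists (CD8 T cells and plasma cells, adjusted p = 0.034 each). Marker lists past the threshold were 3 in the main analysis, 1 with voom, 6 with no low-count filter and 5 with the CPM filter. The Th2, Treg, Th17, IL-2 and STAT5 and both interferon lists passed by camera in 19 of 19 refits. The other called lists did not: Tfh was lost in 6, S phase in 4 (replicate block 0.051 among them), MYC targets in 3 and G2 and M phase in 1. The cytotoxic effector list had adjusted p from 0.00964 (without KO 4, downward) to 0.879 without 1 library, and up to 0.978 over its other refits. Among single named genes and Ddx58 left aside, 1105 values kept direction and side, 285 lost and 38 gained significance and 13 changed sign, all of uncalled genes. Ifng was 0.14 with voom, 0.10 with the replicate block and −0.41 to 0.33 without 1 library. Cxcr5 ran from −0.0591 to 0.335 without 1 library. Tbx21 was 0.0907 with GC and length trends removed and −0.0979 to 0.0144 without 1 library, and Mavs 0.0153 and −0.105 to 0.0173. The cause was not tested. The odds ratio near Ddx58 was 1.55 within 20 Mb and 0 within 5 Mb, where 0 of 60 tested genes were called. With 4 libraries per group, the simulated recovery of 36% at a log2 change of 0.5 limits what small changes can be seen.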

Other observations

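The genes below were chosen after their values were seen. Further Th2 cytokine genes did not pass the threshold: Il13 stood at 4.44 ± 4.79 CPM in KO and 23.1 ± 6.8 in WT (log2 −2.37, adjusted p = 0.0607), Il9 had log2 −2.51 (adjusted p = 0.0574) and Il5 −2.65 (adjusted p = 0.160). The Treg gene Ikzf2 had log2 −0.89 (adjusted p = 0.0674). Prdm1, which encodes the transcription factor BLIMP-1, stood at 6.27 ± 6.22 CPM in KO and 24.8 ± 8.1 in WT (log2 −1.98, adjusted p = 0.0863), with KO 4 at 15.54 CPM and the other KO libraries at 2.53 to 4.12 CPM.

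Beside Akr1c18, its paralogs Akr1c12 (log2 −1.87, adjusted p = 0.0125) and Akr1c13 (log2 −1.13, adjusted p = 0.0403) fell in KO, with reads possibly shared between them. Beside Ms4a4b and Ms4a4c, Ms4a4a rose (log2 1.54, adjusted p = 0.0451). Mpeg1, which encodes a pore-forming protein known from macrophages, rose from 1.55 ± 0.57 to 5.24 ± 2.06 CPM (log2 1.75, adjusted p = 0.0340). Within the interferon list, Irf7 had log2 1.46 (adjusted p = 0.0919), while Mx1 had log2 −0.34 (adjusted p = 0.582).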
